A study of Homo sapiens with 4 samples.

How the data were processed

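Gene expression after exposure to a demethylating drug was measured on 4 Agilent arrays of 41000 probes, read in both Cy3 and Cy5, 1 array per cell line. BEAS-2B is a bronchial epithelial line transformed with SV40 that does not form tumours, and it formed the bronchial epithelial group of 1 array. H1993, H1395 and Calu-6 are lung cancer lines and formed the lung cancer group of 3 arrays. Per the labels, cells were seeded at 15% confluence and given 1 µM 5-Aza-2'-deoxycytidine, also called decitabine, from 6 h after plating. The drug is a cytidine analogue that traps DNA methyltransferases, so that methylation is lost as DNA is copied. Cells were grown to 90 to 100% confluence, and 500 ng of total RNA was labelled. RNA of treated cells carried Cy3 and RNA of untreated cells carried Cy5 on all 4 arrays, with no dye swap. Per the labels, BEAS-2B was grown in serum-free medium and the lung cancer lines in medium with serum.

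Per the file headers, the slide was scanned and read with Agilent Feature Extraction 9.5.3.1, and each file holds the mean intensity of a spot and the median intensity of its local background, with no normalization. The deposited files also hold processed intensity values, background-subtracted, detrended across the slide and dye-normalized by the scanner software. They hold the log10 ratio of processed Cy5 over processed Cy3 and, per the file headers, the p-value of that log ratio from an error model within 1 array. The deposited matrix of the series holds log10 ratios of untreated over treated signal. It was checked against the scanner log ratios: 99.4% of probes agreed within 1e-06 on each array, and each column had a median of 0. Signs were turned here, so that a positive value is a higher signal in treated cells.

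Ratios were recomputed from the mean spot intensities in R 4.3.3 with limma (version 3.58.1) and data.table (version 1.17.8). Background was corrected by the normexp method with an offset of 50, and ratios were normalized by loess within each array. The offset pulls ratios of dim probes toward 0. Loess centres each array's ratios on 0 along intensity, so a change shared by most genes cannot be seen. For untreated cells, the Cy5 channel was used after Aquantile normalization between arrays. Probes were kept when well above background by the scanner's call in at least 1 channel on at least 2 of the 4 arrays, which left 28576 probes. The brightest probe stood for each gene, which gave 21587 genes. Symbols came from the files or, for 23434 probes, by matching the file's accession to a reference list of human genes (GRCh38.p14), used for names alone. Of the genes tested, 13619 had a symbol that could be named. Probe coordinates are those of the files, on hg17; no annotation of that build was used here, so exon and UTR positions are not given.

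The precision is limited by the number of arrays. Between 61.8% and 66.1% of probes were well above background for treated RNA, and between 64.3% and 65.5% for untreated RNA. Repeated spots of a probe had an SD of 0.05 to 0.06 log2 within an array, and spike-in transcripts of known ratio gave slopes of 0.908 to 0.931 against the known values. Of 5361 genes with more than 1 probe, 77 had probes over 1 log2 apart in the mean response of the lung cancer lines. On the BEAS-2B array 71 spots had a local Cy5 background over 2 times the array's median, and they carried the probes of 34 genes. The other 3 arrays had 0 such spots. A fold is written as "at least" where 1 channel was not well above background; the dimmer side was then set to the gene's own signal or, if higher, to the floor, the level under which 95% of that channel's probes called below background lay. Where only some lung cancer lines were below background, only those were set to the floor, and in a mean response a line below background in both channels was set to 0. Means and SDs of log2 ratios otherwise used signals as measured.

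The response of the lung cancer lines was the mean log2 ratio of the 3 lines against 0. The difference in response was that mean minus the BEAS-2B ratio, and the untreated comparison was the lung cancer mean minus BEAS-2B in the Cy5 channel. Each was tested with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fits had 2 residual degrees of freedom. The replicates are different lines, so each p measures the spread between lines and not between repeats of a line. The single BEAS-2B array was assumed to vary like the lung cancer arrays. The difference and the untreated comparison share that array and are not independent. Single lines had no replicate and no test; their genes were counted at 2-fold or more with the brighter channel well above background. A further rule of size took genes at least 2-fold lower in untreated cells than in untreated BEAS-2B and at least 2-fold higher after treatment in all 3 lung cancer lines. It also required the treated signal to be well above background and a ratio under 1.5-fold in BEAS-2B. Both criteria share the untreated signal, so the rule was also run on 100 draws of spot noise, in which both criteria shared the noise of the untreated channel. A second run used 100 draws of shuffled data. Other variation of the untreated signal enters both criteria and was not simulated.

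A total of 24 gene lists fixed before the data were examined were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists. Every call was repeated with the correlation estimated from the data. Within a line, a list's median was ranked among 10000 random lists of the same size and intensity. The lists held cancer-testis and germline, interferon-stimulated, antigen presentation, p53 target, cell cycle, stress response, NRF2 target, metallothionein, DNA methylation, methylation-silenced, metastasis suppressor and brain metastasis genes. They also held epithelial adhesion, mesenchymal, distal lung, airway basal, neuroendocrine, fibroblast, leukocyte, imprinted, HOX, ribosomal protein and inflammatory genes, and the serpins, kallikreins and S100 genes. Similarity between lines was the correlation across genes of each pair of arrays, without a p-value, since genes are not independent replicates.

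Genes were named by a rule also fixed before the data were examined. Per comparison it took the 10 genes with the largest change in each direction among those past the threshold. Where fewer passed, it filled up with the genes whose smallest change over the 3 lines was largest. It took the 5 most raised and 3 most lowered genes per line, up to 4 members per list and up to 8 for the list with the largest shift, and DNMT1 and CDKN1A in any case. XIST and Y-linked genes, and probes without a gene symbol, were not named. Not every gene taken by the rule was named in the text.

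The code was tested on simulated data built from the 21587 genes and the measured spread, with 20 draws per comparison. The response test called 2.24% of genes given a 2-fold change, 77.3% of those given 4-fold and 95.5% of those given 16-fold, with 5.75 false calls per draw. The difference test called 0% at 2-fold, 0.149% at 4-fold and 47.4% at 16-fold, with 1.45 false calls per draw. The untreated test called 0% at each of the 3 sizes. The list test called the cancer-testis and germline list, shifted 1.41-fold, in 100% of draws, with genes drawn independently of each other. In the measured data the estimated correlation within a list reached 0.797, for cell cycle genes. The simulation therefore does not cover lists whose genes vary together. The rule of size recovered 100% of genes made to meet it.

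Alternatives tried for each result were the scanner's processed signals, an offset of 0, median centring in place of loess, no filter, a filter on all 4 arrays, the mean over a gene's probes and leaving out each lung cancer line in turn. Where they applied, the deposited matrix, a trended and robust spread estimate, the mean over all 4 arrays, other fold thresholds and an estimated correlation were also tried. Leaving out the spots of high local background was chosen after seeing the data.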

Results

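Treated and untreated RNA of 4 cell lines was compared on 4 arrays, 1 per line. The lines were BEAS-2B, a bronchial epithelial line that served as the control for a general response to the drug, and the lung cancer lines H1993, H1395 and Calu-6. Each array set the RNA of cells grown with 1 µM 5-Aza-2'-deoxycytidine against that of the same line grown without it. Values are log2 ratios of treated over untreated signal after background correction and loess normalization. Means over the lung cancer lines are given with their SD over 3 lines, and single lines have no replicate. Between 61.8% and 66.1% of probes were well above background in the treated channel and between 64.3% and 65.5% in the untreated channel.

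The first comparison asked which genes changed with treatment in the lung cancer lines. The 10 genes named by the rule on the higher side had mean log2 ratios from 1.92 to 4.81. TFPI2, a protease inhibitor of the extracellular matrix, had a mean log2 ratio of 4.72 ± 0.95 (SD, n = 3), with 5.18 in H1993, 3.62 in H1395 and 5.35 in Calu-6, where the signal was at least 26.6-fold higher after treatment. DAZL, an RNA-binding protein of germ cells, had a mean of 4.81 ± 2.07, and GCNA, a germ cell protein listed as ACRC, a mean of 4.51 ± 1.98. CTAG1A, a cancer-testis antigen with a near-identical copy on the same chromosome, had 3.59 ± 0.97. HCLS1, an actin-binding adaptor of blood cells, had 3.39 ± 0.93 in the lung cancer lines and 0.43 in BEAS-2B. The proteoglycan gene SRGN, listed as PRG1, had 2.89 ± 0.59, and PREX1, a Rac exchange factor, 3.49 ± 1.46. Smaller means came from the receptors IL13RA2 (2.31 ± 1.02), FGFR3 (1.99 ± 0.68) and CSF1R (1.92 ± 0.50). Untreated signals were well above background in 1 of the 3 lines for DAZL and IL13RA2 and in 2 for TFPI2, CTAG1A and PREX1. With the others at the floor, the means were at least 4.38 for DAZL, 1.98 for IL13RA2, 4.51 for TFPI2, 3.50 for CTAG1A and 3.15 for PREX1.

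On the lower side stood DDIT4, a stress-induced inhibitor of mTORC1 signalling, at -1.70 ± 0.16 (SD, n = 3) in the lung cancer lines and 0.55 in BEAS-2B. TNFSF10, which encodes the death ligand TRAIL, had -0.83 ± 0.09 in the lung cancer lines and 0.15 in BEAS-2B. The ribosomal protein genes RPS2 and RPL13A had -1.67 ± 0.85 and -0.80 ± 0.16. The 6 probes of RPS2 ranged from -1.67 to -0.23. Also named were ECH1 and CLYBL, which encode mitochondrial enzymes, TRAPPC9, TCAIM and DYNLT2B, with means from -1.20 to -0.83.

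A total of 43 genes were at least 2-fold higher in treated cells in all 3 lung cancer lines, against 0.409 for independent lists, and 31 of the 43 were also at least 2-fold higher in BEAS-2B. Only DDIT4 and RPS2 were at least 2-fold lower in all 3, against 0.0222. With limma, 0 of 21587 genes passed the adjusted threshold. The smallest adjusted p was 0.472, which is also the value of all genes named above for the response. At an unadjusted p under 0.05 there were 2251 genes, 1352 higher and 899 lower, against 1079 by chance. This excess did not hold with a trended and robust spread estimate, which gave 825 genes, 241 of them higher. Nor did it hold without H1993 (850 genes) or without H1395 (876), while there were 3556 without Calu-6, 3480 for the mean over all 4 arrays and 9938 with median centring. The scanner's processed signals gave 7 genes past the threshold, among them DAZL, IL13RA2, PAGE5, CT45A1 and G0S2. Leaving out Calu-6 gave 9, among them GSTP1, GCNA, RHOXF2, SYCP3 and TKTL1, and median centring gave 6325, of which 666 were higher.

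The probes of these genes lay, on hg17, on chromosome 7 at 93161226 to 93161285 for TFPI2, on chromosome 3 at 16603821 to 16603880 for DAZL and on chromosome X at 70616312 to 70616371 for GCNA. The HCLS1 probe lay on chromosome 3 at 122832969 to 122833026, and the DDIT4 probe on chromosome 10 at 73705369 to 73705428.

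**Figure D1:**
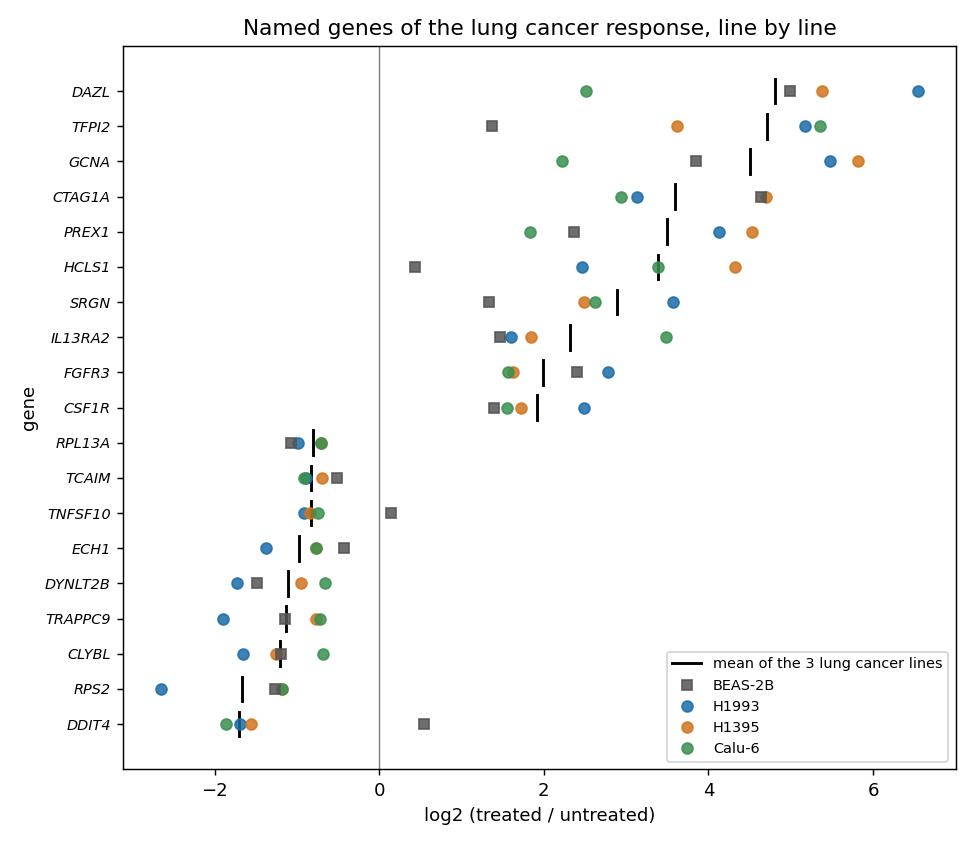
Log2 ratio of treated over untreated signal (horizontal axis) for genes named in the lung cancer response, with circles for the 3 lung cancer lines, a square for BEAS-2B and a vertical bar for the mean of the lung cancer lines. For TFPI2 the BEAS-2B value was 1.37 and the lung cancer values ranged from 3.62 to 5.35, and for DDIT4 the lung cancer values ranged from -1.86 to -1.55 with 0.55 in BEAS-2B.

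Gene groups fixed before the data were examined were then compared with all other genes. Cancer-testis and germline genes rose in the lung cancer lines, with a median of 1.02 over 37 members (adjusted p = 1.36e-14, camera), and the adjusted p was 0.475 with an estimated correlation. The processed signals gave a median of 1.88. Of the 37 members, 29 were higher in all 3 lines and 1 was lower in all 3. Adjusted over the list alone 6 members passed, and over all genes tested 0. DAZL stood first, followed by PAGE5 (3.80 ± 2.13, SD, n = 3), the meiotic chromosome protein gene SYCP3 (3.79 ± 2.56), the transketolase relative TKTL1 (3.70 ± 2.99) and PAGE2 (3.52 ± 2.33). CT45A1 had 3.46 ± 1.98, MAEL 2.54 ± 1.72 and MAGEC1 2.10 ± 1.21. Untreated SYCP3 was well above background in 1 of the 3 lung cancer lines, and PAGE5, PAGE2, CT45A1 and MAEL in 2. With the others at the floor the means were 3.58 for SYCP3, 3.60 for PAGE5, 3.41 for PAGE2, 3.31 for CT45A1 and 2.35 for MAEL. PAGE, CT45 and MAGE genes have close copies, so their probes may read more than 1 copy. Per line, 25 members were at least 2-fold higher in BEAS-2B, 22 in H1993, 23 in H1395 and 4 in Calu-6.

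Interferon-stimulated genes rose, with a median of 0.57 over 36 members (adjusted p = 7.3e-07), and 0.475 was the adjusted p with an estimated correlation. Without H1993 the median was 0.28. Of the 36 members, 17 were higher in all 3 lines, and adjusted over the list alone 0 passed. IFI27 had a mean of 2.12 ± 1.30 (SD, n = 3). IRF7, an interferon regulatory transcription factor, had 2.01 ± 1.86, with 3.36 in H1993, 2.77 in H1395, -0.11 in Calu-6 and -0.31 in BEAS-2B; its 2 probes had means of 0.38 and 2.01. In H1993 17 members were at least 2-fold higher, in H1395 11, in BEAS-2B 6 and in Calu-6 0. Antigen presentation genes had a median of 0.18 and did not pass (adjusted p = 0.172, and 0.00445 without H1395). TAP1 and PSMB8 had 1.26 and 1.55 in H1993 and 0.33 and 0.09 in H1395.

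Genes reported as silenced by methylation in lung cancer rose, with a median of 0.27 over 38 members (adjusted p = 0.00901; 0.475 was the adjusted p with an estimated correlation). By line the medians were 0.282 in H1993, 0.195 in H1395, -0.056 in Calu-6 and 0.185 in BEAS-2B. In the same order 10, 8, 2 and 10 members were at least 2-fold higher. The median difference from BEAS-2B was -0.03, so the rise was not particular to the lung cancer lines. The median was 0.14 without H1993, 0.43 with an offset of 0 and 0.56 with the processed signals. Behind TFPI2 stood NPTX2, a secreted neuronal pentraxin (2.32 ± 2.14, SD, n = 3), the semaphorin gene SEMA3B (1.52 ± 1.37) and SOCS3 (1.39 ± 1.47), whose 2 probes had means of 0.18 and 1.39. NPTX2 had 3.82 in H1993 and 3.27 in H1395, while both channels were below background in Calu-6. SEMA3B had 2.28, 2.34 and -0.05 in H1993, H1395 and Calu-6. Metastasis suppressor genes also rose, with a median of 0.17 over 33 members (adjusted p = 0.0104; 0.475 was the adjusted p with an estimated correlation), and 13 were higher in all 3 lines. Their median was 0.37 without H1395, 0.29 with an offset of 0 and 0.30 with the processed signals. ARHGDIB had 1.71 ± 0.69 and the metalloproteinase inhibitors TIMP1 and TIMP2 had 1.45 ± 0.85 and 1.07 ± 0.58. KISS1 had 2.07 in H1993 and 0.42 or less in the other lung cancer lines. Genes linked to brain metastasis, the subject named by the series, had a median of 0.29 over 23 members and an adjusted p of 0.0545, so their result depended on the processing. They passed with the processed signals (0.0188), an offset of 0 (0.0464), median centring (0.0108), no filter (0.0329) and the mean over probes (0.0497). They also passed without H1395 (0.0145) and without H1993 (0.0404), where the median was 0.06, but not with the filter on all 4 arrays (0.113) or without Calu-6 (0.211). Among the members, the matrix metalloproteinase genes MMP1 (2.29 ± 1.72) and MMP9 (1.88 ± 0.98) were at least 2-fold higher in all 3 lines, and PGF had 0.96 ± 0.31.

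Of the other groups, serpins, kallikreins and S100 genes rose with a median of 0.47 (adjusted p = 0.00148; 0.475 was the adjusted p with an estimated correlation), led by S100A4 (2.27 ± 1.70, SD, n = 3) and S100A2 (1.75 ± 0.89); the processed signals gave a median of 0.84. Mesenchymal genes rose with a median of 0.27 (adjusted p = 0.00192, and 0.475 with an estimated correlation), with SNAI1 at 1.55 ± 0.46 and VIM at 3.44 in H1395 and -0.64 in Calu-6. Their median was 0.10 without H1993, 0.52 with an offset of 0 and 0.66 with the processed signals. Epithelial adhesion genes rose with a median of 0.14 (adjusted p = 0.00901, and 0.475 with an estimated correlation), among them LAMB3 at 2.18 ± 0.56 and CDH1 at 0.93 ± 1.04, which was below background in Calu-6; their median was 0.09 without H1993 and 0.26 without Calu-6. Airway basal and secretory markers rose with a median of 0.34 (adjusted p = 0.0364, and 0.48 with an estimated correlation), and TP63 had 3.90 in H1993 and was at least 8.07-fold higher in H1395. Their median was 0.16 without H1395, 0.76 without Calu-6, 0.21 with no filter and 0.12 with the filter on all 4 arrays. P53 targets had a median of 0.37 (adjusted p = 0.00206, and 0.517 with an estimated correlation), which was 0.14 without H1395 and 0.66 without Calu-6. By line, without a test between lines, the medians were 0.47 in H1993, 0.78 in H1395 and -0.06 in Calu-6, where 0 members were at least 2-fold higher and 3 lower. TP53INP1 had 1.73 ± 1.43 and PHLDA3 1.14 ± 0.71, and CDKN1A had 0.71 ± 0.88. Inflammatory cytokine and chemokine genes had a median of 0.22 (adjusted p = 0.0449, and 0.48 with an estimated correlation), which was -0.07 without Calu-6 and 0.41 without H1993. In H1993 1 member was at least 2-fold higher and 5 were lower. The median was 0.34 with an offset of 0, 0.37 with the processed signals and 0.03 with the filter on all 4 arrays. IL6 had 3.13 in H1993, and CXCL2 had -2.40 there.

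HOX genes rose with a median of 0.19 (adjusted p = 0.0104, and 0.475 with an estimated correlation), with HOXD1 at 1.30 ± 1.11 (SD, n = 3), which was well above background in 1 of the 3 untreated lung cancer lines. Their median was 0.07 without H1395, 0.33 without Calu-6, 0.33 with the processed signals, 0.29 with an offset of 0, 0.08 with no filter and 0.32 with the filter on all 4 arrays. Ribosomal protein genes fell, with a median of -0.48 over 38 members (adjusted p = 1.53e-15, and 0.475 with an estimated correlation). Of these, 33 were lower in all 3 lung cancer lines, 5 passed when adjusted over the list alone, and the medians were -0.80 in H1993, -0.33 in H1395, -0.38 in Calu-6 and -0.50 in BEAS-2B. Their median difference from BEAS-2B was 0.01, and the processed signals gave a median of -0.33 in the lung cancer lines. Treated RNA carried the same dye on every array. A constant part of dye bias can therefore not be told apart here from a response shared by all lines. Cell cycle genes (median 0.11, adjusted p = 0.06), stress response genes (-0.23, 0.279), NRF2 targets (-0.09, 0.243) and metallothioneins (0.08, 0.41) did not pass. Neither did distal lung markers (0.09, 0.41), neuroendocrine markers (0.14, 0.227), leukocyte markers (0.11, 0.06) or fibroblast markers, whose median was -0.00 and whose mean was 0.38 (0.45). Some of these passed elsewhere. Cell cycle genes did with no filter (0.0262), the mean over probes (0.046) and without H1395 (1.08e-09), and metallothioneins without H1395 (0.0228). Stress response genes did without H1993 (0.035) and without H1395 (0.00445). Leukocyte markers did with the processed signals (0.0281), an offset of 0 (0.0471), the filter on all 4 arrays (0.0279), without H1993 (0.0404) and without H1395 (0.00652). Median centring called cell cycle (0.00838), stress response (0.00288) and NRF2 (0.0137) genes lower than other genes. It called leukocyte (0.0067) and fibroblast (0.0339) genes higher. For cell cycle genes this direction was opposite to that with no filter and with the mean over probes.

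In all, 14 of the 24 lists passed at the preset correlation, 13 higher and 1 lower, and 0 with the estimated correlation. The latter test rested on 2 residual degrees of freedom, so its 0 cannot tell genes that vary together from low power. HOX genes lost their call there although their estimated correlation, -0.00976, was below the preset 0.01. Relative to the median of all genes, median centring gave 0.58 for methylation-silenced, 0.61 for mesenchymal, 0.53 for HOX, 0.40 for imprinted, 0.55 for inflammatory and -1.40 for ribosomal protein genes, and 0.80 for the serpins, kallikreins and S100 genes. It ended the calls of the p53 target, DNA methylation, metastasis suppressor and epithelial adhesion lists. Leaving out H1395 ended those of the p53 target, epithelial adhesion, airway basal, imprinted, HOX and inflammatory lists, and leaving out Calu-6 those of the metastasis suppressor and inflammatory lists. Here the filter on all 4 arrays ended those of the airway basal, imprinted and inflammatory lists.

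**Figure D2:**
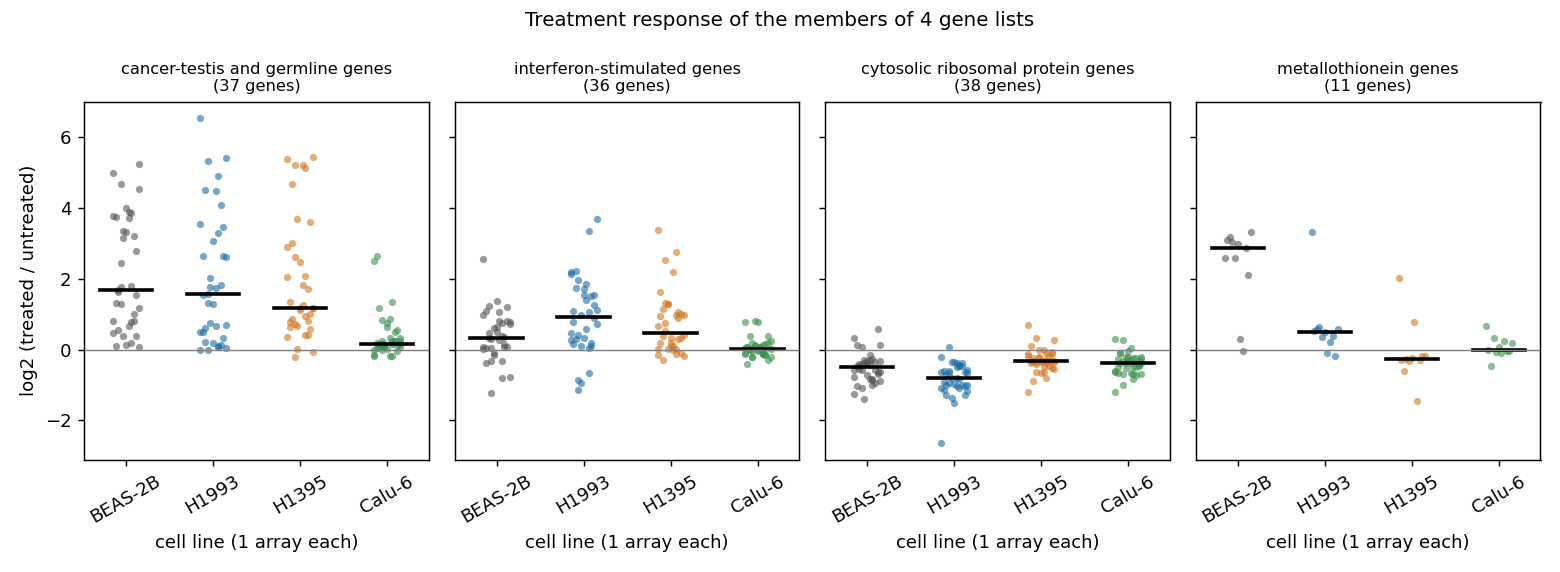
Log2 ratio of treated over untreated signal (vertical axis) of the members of 4 gene lists in each line, with a point per gene and a line at the median. Cancer-testis and germline genes had medians of 1.69 in BEAS-2B, 1.57 in H1993, 1.19 in H1395 and 0.17 in Calu-6, and metallothioneins had 2.87 in BEAS-2B.

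The next comparison described each line by itself, with no test. H1993 had the most genes at least 2-fold apart between treated and untreated cells, with 1476 higher and 719 lower. BEAS-2B had 1161 higher and 287 lower, H1395 had 979 higher and 141 lower, and Calu-6 had 132 higher and 102 lower. The signal in untreated cells was not well above background for 96 of the higher genes in BEAS-2B, 245 in H1993, 188 in H1395 and 21 in Calu-6. The X-linked germline genes VCX3A, VCX2 and VCX, which have close copies, were 57.8-fold, 49.5-fold and 37.2-fold higher in treated BEAS-2B, and TKTL1 was 37.8-fold higher there. The 2 probes of VCX2 lay over 1 log2 apart in the lung cancer lines, and the fold is that of the higher one, the lower having a mean of 2.48. DAZL was at least 31.9-fold higher in BEAS-2B, 93.2-fold in H1993 and at least 28.5-fold in H1395. In H1993, the germline transcription factor gene DMRTB1 was 132-fold higher, and the prohormone convertase gene PCSK1 76.8-fold and RARRES1 65.4-fold higher. VCX3A was 60.8-fold higher in H1993. H1993 also had HOPX, a homeobox regulator of distal lung, 15.5-fold lower (-3.96), LHPP at -3.05 and the fatty acid desaturase gene SCD at -2.89.

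In H1395 GSTP1, a glutathione transferase, was 68.4-fold higher. It was 58.1-fold higher in H1993, 1.58-fold in BEAS-2B and 1.16-fold in Calu-6, and untreated log2 signals were 10.09 in H1395, 10.25 in H1993, 16.35 in BEAS-2B and 16.23 in Calu-6. RHOXF2 was at least 32.4-fold higher in H1395, GCNA 56.3-fold and TKTL1 43.9-fold. The 2 probes of RHOXF2 had lung cancer means of 1.49 and 3.99, and the fold is that of the higher one. The most lowered genes of H1395 were APCS, AGT and PPP1R1A at -2.37, -2.27 and -2.17. Cell cycle genes in H1395 had a median of -0.38, with 0 members at least 2-fold apart, against 0.59 in BEAS-2B, 0.48 in H1993 and 0.26 in Calu-6.

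In Calu-6, TFPI2, IL13RA2, HCLS1, CTAG1A and G0S2, an inhibitor of lipolysis, were the most raised, with G0S2 7.78-fold and IL13RA2 11.2-fold higher. The most lowered were HMOX1, GDF15 and DDIT3. HMOX1, a haem oxygenase induced by oxidative stress, was 10.7-fold lower (-3.42), GDF15 7.38-fold lower (-2.88) and DDIT3, a transcription factor of the unfolded protein response, 6.39-fold lower (-2.68). Of 19 stress response genes, 11 were at least 2-fold lower in Calu-6, among them TRIB3 at -2.55 and ASNS at -1.32. The other lines had 4, 1 and 1 such genes in BEAS-2B, H1993 and H1395.

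The 3 most lowered genes of BEAS-2B by the rule, POU3F1, ERI2 and TMEM260, lay on spots with a local Cy5 background of 574.5, 1606 and 904 against an array median of 61. Without such spots the 3 most lowered were NIBAN1 (-2.24), LHPP (-2.11) and GAS5 (-2.04), a choice made after seeing the data. LHPP had probes over 1 log2 apart in the lung cancer lines. The share of higher genes among those at least 2-fold apart was 80.2% in BEAS-2B, 67.2% in H1993, 87.4% in H1395 and 56.4% in Calu-6. With median centring the shares were 78.5%, 17.8%, 17.2% and 8.64%, and with the scanner's processed signals 64.3%, 57.4%, 69.5% and 52.9%.

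**Figure D3:**
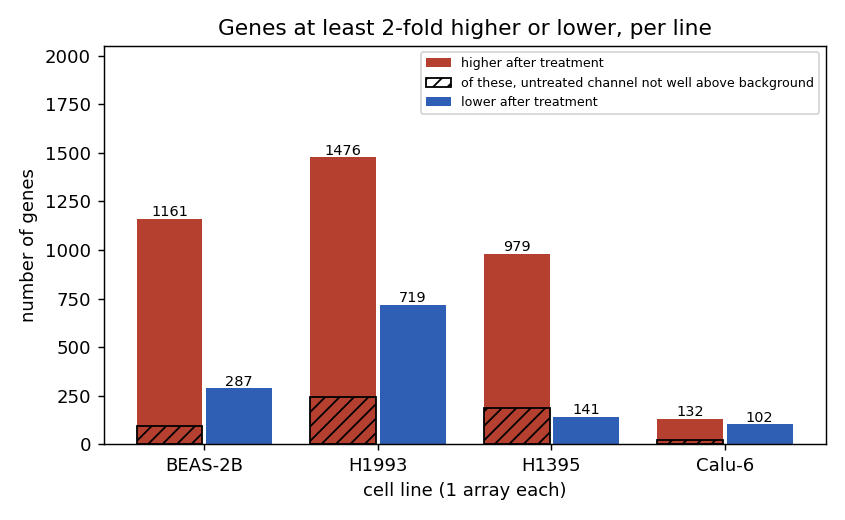
Number of genes at least 2-fold higher (red) or lower (blue) in treated than in untreated cells, per line, with the hatched part for higher genes whose untreated signal was not well above background. H1993 had 1476 higher and 719 lower genes and Calu-6 had 132 and 102, while with median centring lower genes outnumbered higher ones in the 3 lung cancer lines.

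The difference in response between the lung cancer lines and BEAS-2B addressed which changes were not part of a general response to the drug. BEAS-2B also differed in its medium, which cannot be told apart from the line here. TFPI2 was 3.35 higher on the log2 scale in the lung cancer lines than in BEAS-2B (5.18, 3.62 and 5.35 against 1.37), and HCLS1 was 2.96 higher. RPL22L1 and CLGN, at 2.00 and 1.95, had low ratios in BEAS-2B (-1.80 and -1.91) and mean ratios of 0.20 and 0.04 in the lung cancer lines. The other 6 genes named on this side, POU3F1, ERI2, TMEM260, TGFBRAP1, TRIM15 and SLC1A2, lay on spots of high local background on the BEAS-2B array. Without those spots the next genes were SNHG5, SDSL, ATP2C2, RPS6KA2, SULF1 and B3GNT9.

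On the other side, several genes were raised most in BEAS-2B. The cancer-testis antigen gene MAGEA1 was at least 23.5-fold higher in treated BEAS-2B and had a mean ratio of 0.73 ± 0.43 (SD, n = 3) in the lung cancer lines, and MAGEA4 was 15.9-fold higher in BEAS-2B with a lung cancer mean of 1.02 ± 0.34 (untreated signal well above background in 2 of the 3 lines). Before treatment the lung cancer lines already exceeded BEAS-2B at least 8.01-fold for MAGEA1 and by 1.43 log2 for MAGEA4. For FGFBP1 and CRYGC, named below, the untreated difference was instead -1.64 and -0.45, with signals below background at the floor. QPRT, an enzyme of NAD synthesis, was 10.7-fold higher in BEAS-2B with a lung cancer mean of 0.10 ± 0.19. ID1, an inhibitor of differentiation, was 11.3-fold higher, TMT1A 15.8-fold, FGFBP1 9.87-fold and the lens gene CRYGC 7.97-fold. MT1B, MT2A and MT1G, which encode metal-binding metallothioneins, were 10.1-fold, 9.02-fold and 8.60-fold higher in BEAS-2B, with lung cancer means of 0.20, -0.15 and 0.08.

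With limma, 0 genes passed for the difference (smallest adjusted p 0.0644, for POU3F1 on its bright spot), and 1198 had an unadjusted p under 0.05, 318 higher and 880 lower, against 704 without H1395 and 2954 with median centring. Adjusted p was 0.77 for TFPI2 and HCLS1 and ranged from 0.336 for QPRT to 0.77 for FGFBP1 on the other side. No filter gave 4 genes, the filter on all 4 arrays gave 2 and median centring gave 3, all with probes on spots of high local background.

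The untreated comparison showed how the lung cancer lines differed from BEAS-2B before the drug. BEAS-2B was 1 array of a line transformed with SV40 and grown without serum, while the lung cancer lines had serum. Cancer, line, transformation and medium can therefore not be told apart in these differences. KRT5, a basal keratin, was at least 165-fold lower in the lung cancer lines, KRT17 at least 74.1-fold and the protease inhibitors CSTA and CST6 at least 97.6-fold and 65.2-fold. EFEMP1, a matrix glycoprotein, was at least 122-fold lower, the tripartite motif gene TRIML2 at least 40.6-fold, the phosphatase gene INPP5D at least 39.8-fold and the pore-forming GSDME at least 42.9-fold. Of the 3 untreated lung cancer lines, 0 were well above background for KRT5 and TRIML2, 1 for CSTA and INPP5D, and 2 for KRT17, CST6, EFEMP1 and GSDME. ERI2 and POU3F1, also named here, lay on the spots of high local background. Higher in the lung cancer lines were MLPH, a melanosome transport adaptor, 109-fold (6.77 ± 0.38, SD, n = 3), the neuropeptide gene GAL 150-fold (7.23 ± 1.37) and IGFBP2 58.6-fold. The trefoil factor gene TFF1 was at least 195-fold higher, SLCO4A1 at least 41.0-fold and TSPAN8 at least 73.5-fold. PRSS36, BMERB1, HPDL and HS6ST2 were 23.7-fold to 38.1-fold higher.

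In the same comparison 701 genes were at least 2-fold lower than in BEAS-2B in all 3 lung cancer lines and 510 at least 2-fold higher. The limma test of this comparison called 0% of genes at 16-fold in the simulation. A lack of calls in it therefore does not show that no gene differed. Among the lists, p53 targets were lower (median -0.64, adjusted p = 0.00211, and 0.769 with an estimated correlation), as were interferon-stimulated genes (-0.68, adjusted p = 0.00325, and 0.802 with an estimated correlation) and DNA methylation genes (-0.56, adjusted p = 0.0108, and 0.802 with an estimated correlation). TP53INP1 was 3.72-fold lower and PHLDA3 6.68-fold lower. Airway basal and secretory markers were lower (-0.14, adjusted p = 0.00325, and 0.769 with an estimated correlation), with TP63 at least 29.7-fold lower and well above background in 1 of the 3 lines. Of 15 members, 6 were lower in all 3 lines and 2 were higher; the median was above 0, at 0.01, without H1993 and was -0.28 without Calu-6. NRF2 targets were higher (1.24, adjusted p = 0.00117, and 0.769 with an estimated correlation), with AKR1C3 9.91-fold higher. Genes linked to brain metastasis were higher (1.05, adjusted p = 0.00835, and 0.802 with an estimated correlation), with MMP1 at least 17.1-fold and ANGPTL4 6.18-fold higher. With limma, 0 genes passed (smallest adjusted p 0.33), and 1041 had an unadjusted p under 0.05, 408 higher and 633 lower. No filter gave 2001. Leaving out Calu-6 ended the calls of the interferon and brain metastasis lists (medians -0.53 and 0.68), and leaving out H1395 that of the DNA methylation list (-0.35). The interferon median was -0.40 without H1993 and -1.19 without H1395, and the NRF2 median 0.73 without H1395. No filter ended the call of the brain metastasis list (0.69) and the filter on all 4 arrays that of the airway basal list (-0.04).

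The series looked for genes held down in the lung cancer lines that return with demethylation. In this comparison 2 genes met the rule: HCLS1 and COL16A1, a collagen. Low here means low against BEAS-2B, which also differed in its medium. Untreated HCLS1 was 36.4-fold lower in the lung cancer lines than in BEAS-2B, and it was 5.51-fold higher after treatment in H1993, 19.9-fold in H1395 and 10.5-fold in Calu-6 against 1.35-fold in BEAS-2B. Untreated COL16A1 was 24.0-fold lower, and it was 8.65-fold, 2.35-fold and 2.13-fold higher after treatment in H1993, H1395 and Calu-6 against 1.33-fold in BEAS-2B. The COL16A1 probe lay on chromosome 1 at 31787268 to 31787327 on hg17. Over 100 draws spot noise alone gave 0 genes. Shuffled data gave a mean of 0.22 genes and at most 2, which equals the number that met the rule. Spot noise, with an SD of 0.05 to 0.06 log2, is far smaller than the 2-fold thresholds. Its count of 0 therefore could not decide whether these genes stand out. Variation of the untreated signal beyond spot noise was not simulated.

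When the rule had to hold in 2 of the 3 lung cancer lines, 49 genes met it. Spot noise alone gave 0, while shuffled data gave a mean of 14.96 (SD 3.6) and at most 23 over 100 draws. The 49 genes included IRF7, TP53INP1, CSTA and SEMA3B. Chosen after their values were seen, EMILIN2 (2.96 and 3.28 in H1993 and H1395), SULF2 (2.23 and 3.78) and RAC2 (2.03 and 2.78) were also among them. Of genes low in a line, 445 were raised at least 2-fold in H1993, 278 in H1395 and 41 in Calu-6, against 187, 142 and 15 for independent criteria. These were 16.3%, 8.87% and 1.67% of the low genes, against 5.47%, 3.8% and 0.476% of other genes. Both criteria share the untreated signal, so independence is not a full baseline. Of the genes low and raised, 258, 156 and 13 were under 1.5-fold in BEAS-2B. GSTP1, low in H1993 and H1395, missed the rule because it was 1.58-fold higher in BEAS-2B. Without Calu-6 the rule gave 45 genes, without H1395 4 and without H1993 3. HCLS1 and COL16A1 were among them each time. The rule all but ensures this, since a gene that meets it in 3 lines also meets it in 2 of them. The 1.5-fold threshold and an offset of 0 gave 6 genes each, the scanner's processed signals 8 and median centring 4, of which 1 was shared.

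Last, the responses of the lines were compared with each other across 21587 genes. By correlation H1993 and H1395 were the most alike, with a Pearson correlation of 0.545 (Spearman 0.483). They shared 489 genes at least 2-fold higher, 7.31 times the 66.9 of independent lists, while the 3 pairs with Calu-6 shared 8.20 to 8.73 times their own number. Calu-6 had 0.20 (0.155) with H1993 and 0.139 (0.062) with H1395, and it had 0.357 (0.361) with BEAS-2B. BEAS-2B had 0.374 (0.29) with H1993 and 0.342 (0.246) with H1395. In Calu-6 and BEAS-2B 62 genes were at least 2-fold higher in both, against 7.1. These are 6 correlations across genes, which are not independent replicates, and no p was computed. The median of the 6 was 0.35, and all arrays carried the same dye orientation.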

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

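The tests of the metallothionein genes and of the genes raised on every array were chosen after those results were seen, except for 1 planned test of dye bias, and the test of the breast line labels was chosen before. In each of 7 gene lists the response of the lung cancer lines differed from that of BEAS-2B in a test of the difference itself (camera on the contrast), lower in the lung cancer lines each time. None of the 7 passed with an estimated correlation, and BEAS-2B is a single array assumed to vary like the others.

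Metallothioneins, small proteins that bind zinc and copper, stood farthest apart. Their median difference was -2.80 (adjusted p = 2.16e-13, and 0.795 with an estimated correlation), and it was lower in the lung cancer lines for 11 of 11 members. In BEAS-2B the median ratio was 2.87 and 9 of 11 members were at least 2-fold higher after treatment, while the medians were 0.49 in H1993, -0.26 in H1395 and 0.00 in Calu-6. H1993 and Calu-6 turned below 0 with median centring. MT1M differed from the rest, with 2.58 in BEAS-2B, 3.34 in H1993 and 2.04 in H1395, and MT1F had -0.03 in BEAS-2B. The call held in 11 of 11 alternatives.

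Dye bias of the probes would be the same on every array and would cancel in this difference, yet the upper quartile over the members was -1.40. None of the members lay on the bright spots of the BEAS-2B array (0 members). Probes of near-identical copies may have read 1 transcript: 8 members lay within 1 log2 unit of each other in BEAS-2B, so the number of genes that responded cannot be told apart from a single strong one. The culture medium cannot be told apart from the line either, since 1 line, BEAS-2B, was grown without serum. Whether the difference belongs to BEAS-2B alone or to non-cancer lines in general stays open, since BEAS-2B was the only such line.

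Cell cycle genes had a median difference of -0.49 (adjusted p = 0.00113, and 0.843 with an estimated correlation), lower for 29 of 38 members, and the call ended without H1395 (adjusted p 0.0849, median -0.28). Cancer-testis and germline genes had -0.36 (0.00338, and 0.843 with an estimated correlation), lower for 29 of 37 members, and the call ended with an offset of 0, with median centring, where the tested direction turned, and without Calu-6, where the median was 0.06. Their median was -0.77 without H1993, -0.75 without H1395, -1.28 with the processed signals, -1.24 with the filter on all 4 arrays and -0.18 with no filter. NRF2 targets had -0.42 (0.00338, and 0.795 with an estimated correlation), lower for 16 of 18 members, and the call held in 11 of 11 alternatives. Inflammatory cytokine and chemokine genes had -0.37 (0.0243, and 0.796 with an estimated correlation), lower for 18 of 22 members, and the call held in 8 of 11; the median was -0.24 without H1993 and -0.60 with the processed signals. Serpins, kallikreins and S100 genes had -0.25 (0.0308, and 0.796 with an estimated correlation), lower for 12 of 18 members, and the call held in 7 of 11; the median was -0.56 without H1993, -0.66 with the processed signals and -0.11 with no filter. Metastasis suppressor genes had -0.27 (0.033, and 0.796 with an estimated correlation), lower for 22 of 33 members, and the call held in 6 of 11; the median was -0.17 without H1395 and -0.18 without Calu-6. Relative to the median of all genes, median centring gave -0.82 for cell cycle, -0.78 for NRF2 target, -0.17 for cancer-testis, -0.07 for inflammatory and -0.44 for metastasis suppressor genes, and -0.49 for the serpins, kallikreins and S100 genes.

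Of the genes at least 2-fold higher in all 3 lung cancer lines, 31 were also at least 2-fold higher in BEAS-2B, against 0.022 expected on all 4 arrays for independent lists. Treated RNA carried Cy3 on each array, so dye bias could raise a gene everywhere. The test planned for this needed genes past the adjusted threshold, and there were 0. Dye bias as the whole change would give the same ratio on each array, but over these 31 genes H1993 exceeded Calu-6 by a median of 2.45, with a lower quartile of 0.91. A constant part of dye bias stays open, above all for small values alike on all arrays, and so does a response shared by all lines.

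The last point concerns the labels. The description field of each array names breast lines, MCF_10A and sublines of MDA-MB-231, while titles and source names give the lung lines used here. If the 3 lung cancer arrays held sublines of 1 breast line, their untreated channels should correlate across genes above 0.95. The highest of the 3 correlations was 0.887 and the lowest 0.864, against 0.873 to 0.893 with BEAS-2B and 0.961 to 0.992 between treated and untreated cells of 1 line. The last range is between both channels of the same array, so it is not a like measure for different arrays. The 3 arrays therefore did not behave as sublines of 1 line. Wrong labels of another kind stay open for any of the arrays, that of BEAS-2B included, since no reference profile of the lines was used here.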

How the results depend on the processing

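The alternatives were set before the data were examined, except that leaving out the spots of high local background was chosen after seeing the data. Of the main counts and values recomputed, 95 stayed on their side or within 1.5 times and 36 moved; of the list results 227 were the same, 25 became calls, 29 lost their call and 6 turned; of the named gene values 899 were the same, 106 moved, 29 became calls and 0 turned. The calls of the untreated comparison could not show stability, since its test called 0% of genes even at 16-fold in the simulation. The median correlation between lines ranged from 0.316 to 0.397. The count of genes past the threshold in the response was 0 in the lung cancer lines but 7 with the scanner's processed signals and 7 with the deposited matrix. It was 6325 with median centring, of which 666 were higher; it left the median of all genes at -0.37. It ranged from 0 to 9 when 1 lung cancer line was left out, with 9 without Calu-6. At an unadjusted p under 0.05 the response had 2251 genes, but 825 with a trended and robust spread estimate, 850 without H1993, 876 without H1395, 3556 without Calu-6, 3480 for the mean over all 4 arrays and 9938 with median centring. The difference had 1198, but 704 without H1395 and 2954 with median centring, and the untreated comparison 1041, but 2001 with no filter. For the difference, median centring gave 3 genes, no filter 4 and the filter on all 4 arrays 2. Counts of genes at least 2-fold apart summed to 4997 over the lines, to 1696 at 3-fold, 9673 with the processed signals, 9671 with the matrix and 12279 with median centring. At 3-fold BEAS-2B, H1993, H1395 and Calu-6 had 446, 743, 453 and 54. The processed signals gave 2819, 3885, 2260 and 709, and the matrix 2819, 3885, 2259 and 708. An offset of 0 gave 1774 in H1395 and 447 in Calu-6, and median centring gave 5344 in H1993, 4347 in H1395 and 1123 in Calu-6. The rule for genes low and then raised gave 6 genes at 1.5-fold, 49 for 2 of 3 lines, 8 with the processed signals, 6 with an offset of 0, 4 with median centring and 3 to 45 without 1 lung cancer line. With an estimated correlation 0 lists passed, in a test that rested on 2 residual degrees of freedom. Lists that turned direction were not called in the response: cell cycle genes (adjusted p 0.00838) and metallothioneins (0.104) turned with median centring. Relative to the median of all genes, inflammatory genes had medians from -0.07 to 0.55. Without 1 lung cancer line the adjusted p ranged from 1.08e-09 to 0.563 for cell cycle genes, 0.0228 to 0.563 for metallothioneins, 0.00445 to 0.721 for antigen presentation genes and 0.00445 to 0.127 for stress response genes; the first 3 turned without H1993 and the last without Calu-6. The cause was not tested for these changes. Signal over background limits the smallest ratios: folds of genes below background in 1 channel are bounds. No paired analysis beyond the ratio within each array was possible because each line has 1 array, and a slide term was not run because all arrays lay on 1 slide.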

Other observations

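The test of drug handling in Calu-6 was chosen before its result was seen. The DNA methylation genes themselves rose in the lung cancer lines, with a median of 0.18 over 14 members (adjusted p = 0.0104, and 0.475 with an estimated correlation), and 2 members passed when adjusted over the list alone. Median centring ended the call (adjusted p 0.961). UHRF1, which brings DNMT1 to newly copied DNA, had 1.14 ± 0.55 (SD, n = 3) and 1.70 in BEAS-2B. DNMT3B, a de novo methyltransferase, had 1.09 ± 0.38 and 1.40 in BEAS-2B, and both were higher on all 4 arrays. DNMT1, the maintenance enzyme that the drug traps, had 0.29 ± 0.31. The methyl-binding proteins MBD1 and MBD3 had 0.52 ± 0.45 and 0.52 ± 0.34.

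Imprinted genes rose with a median of 0.17 over 19 members (adjusted p = 0.0259, and 0.48 with an estimated correlation), and their mean was 0.51. The call ended without H1395 (adjusted p 0.0559) and with the filter on all 4 arrays (0.139), where the median was 0.00; it was 0.42 with the processed signals and 0.46 with an offset of 0. The cell cycle inhibitor CDKN1C had 2.14 ± 1.55 (SD, n = 3), and DLK1 had 3.24 in H1993 and 2.95 in H1395 while it was below background in Calu-6 and BEAS-2B. H19 had 2.02 ± 0.53, with a second probe at 0.15, and IGF2 had 1.46 ± 0.63. Fibroblast and leukocyte markers did not pass as lists. COL1A2, a fibrillar collagen gene, had 4.15 in H1993, where it was 17.7-fold higher, and the leukocyte gene CORO1A had 0.76 ± 0.20 in the lung cancer lines and 1.24 in BEAS-2B.

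Calu-6 had the fewest responding genes, 234 at least 2-fold apart against 1120 to 2195 in the other lines. Of 13 cancer-testis genes at least 2-fold higher in H1993 and H1395 and not in Calu-6, 4 were well above background in untreated Calu-6 and 7 in treated Calu-6. A hypothesis was that Calu-6 may take up or activate less of the drug. Decitabine enters cells through transporters such as that of SLC29A1, is phosphorylated by the kinase of DCK and is broken down by the deaminase of CDA. Of these 3 genes, 0 were at least 2-fold apart in untreated Calu-6 from every other line in the direction of less active drug. DCK was 9.53 in Calu-6 against 9.19 to 10.13 in the other lines, SLC29A1 11.37 against 10.72 to 11.83 and CDA 7.11 against 6.90 to 7.73. The mRNA levels therefore showed no shift of that size toward less active drug, but they cannot decide the hypothesis. They came from arrays without replicates, and a difference under 2-fold would be missed. DCK was lowest in H1395, and CDA in untreated Calu-6 lay close to the floor of 6.71. Protein levels, growth rate and the extent of demethylation were not measured. Of 19 stress response genes, 11 were at least 2-fold lower in treated than in untreated Calu-6.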
